A study of Mus musculus with 18 samples.

How the data were processed

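The samples were 18 RNA-seq libraries from mouse deep digital flexor tendon, 3 in each of 6 groups formed by genotype (WT or PAI-1 KO) and state (uninjured, 2 weeks or 4 weeks after a partial laceration). Per the labels, total RNA was extracted with the RNeasy Plus Micro or the Arcturus PicoPure kit, and which kit served which sample is not given in the sources used here. The libraries were made with the NexteraXT kit, which does not mark the strand a transcript came from. Per the labels, the authors' pipeline used Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, R 3.3.2 and DESeq2 1.14.1 on the GRCm38.p5 build. The annotation release and the strand setting are not given in the sources used here. The table deposited by the authors holds counts: whole-number read counts per gene symbol, 49568 symbols by 18 libraries, not scaled, with 0 columns that belong to no sample. The total count per library ran from 9705922 to 25247658, so that 3 counts corresponded to a CPM of 0.121 to 0.307.

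The counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16844 genes, and libraries were scaled by TMM. All 18 libraries entered one quasi-likelihood fit of 6 groups (glmQLFit and glmQLFTest, common dispersion 0.336), with 11 contrasts: each injured state against uninjured and 4 weeks against 2 weeks within each genotype, KO against WT in each state, and the difference between genotypes in the response to injury at 2 and at 4 weeks. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values (the usual library-scaled count unit of edgeR) are on the TMM scale.

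Named genes followed a rule fixed before the data were examined. In each contrast these were the 10 higher and 10 lower genes with the largest absolute log2 fold change among called genes with an average of at least 10 CPM in the higher group and every library of one group above every library of the other. For 3 libraries against 3, chance alone separates 10% of genes in this way. The separation was not asked of the differences between genotypes in response, and genes with Gm, Rik, immunoglobulin or T cell receptor names were counted but not named. Up to 4 members with the smallest p of each gene list were added, and where fewer than 5 genes passed, the 5 with the smallest p were named. A fold against a group with no counts was computed against 3 counts over the group and is given as at least that size; for 1 to 3 counts the ratio of CPM is given with its exact 95% counting interval. These floors and intervals cover counting error only.

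There were 38 gene lists, also fixed before the data were examined, and all had at least 5 tested members. Each list was tested in each of the 11 contrasts with camera (limma, log values with a prior count of 2, preset inter-gene correlation of 0.01), with Benjamini-Hochberg adjustment over the 418 tests. The members called are counted over all genes tested and adjusted over the list alone. Camera with a correlation estimated per list and fry were run as alternatives. List medians were also computed with groups that held no counts set at 3 counts. Gene coordinates came from the GENCODE annotation of GRCm38, which matched 16610 of the tested genes (98.6%). Called genes near Serpine1 were compared with genes elsewhere by two-sided Fisher's exact tests with windows of 5, 10 and 20 Mb.

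The alternatives tried were DESeq2 size factors in edgeR, no low-count filter, a DESeq2 1.42.0 Wald test, limma voom with sample quality weights, only the groups compared in the fit, an absolute log2 fold change of at least 1, each library left out in turn, uninjured libraries whose titles share a number summed, and the summed skeletal muscle list as a covariate. Added after the data were seen were a fit without KO uninjured replicates 1 and 2 together, the summed endothelium list as a covariate, and KO minus WT averaged over the 3 states. The fit was tested on simulated data with 200 changed genes of 2-fold to 16-fold. No sample was left out. Sequence reads were not used here, so alignment, strand and exon use were not analysed here.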

Results

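Gene expression was measured by RNA sequencing in deep digital flexor tendon of WT mice (C57Bl/6J) and of mice with a targeted Serpine1 gene (B6.129S2-Serpine1tm1Mlg/J, PAI-1 KO). Tendons were uninjured or were collected 2 or 4 weeks after a partial laceration, with 3 libraries in each of the 6 groups. Total counts per library were 9705922 to 25247658, lowest in KO 4 weeks replicate 3 and highest in WT uninjured replicate 1. Titles in both uninjured groups give a left and a right tendon the same number. The labels do not say that each library is a separate animal, so p-values measure the spread between these samples. That spread was taken in 1 fit over all 6 groups, which differed in it. Between libraries of a group, Pearson r of log CPM was 0.816 to 0.901 in KO uninjured. It was 0.875 to 0.922 in injured KO and 0.931 to 0.971 in the WT groups. A p for 1 comparison thus also reflects the spread of groups outside it. All 18 libraries had 0 counts of Xist, and Ddx3y had 480 to 1721. Errors are SE with n = 3 libraries per group unless stated, and adjusted p come from edgeR. A signed or unlabelled value after a gene is its log2 fold change, positive where the group named as changed was higher, and a bare value after it in brackets is its adjusted p. None of the 142 list calls made by camera with its preset correlation held with an estimated correlation (lowest adjusted p = 0.0955). Each such p is given beside its list where a call is described. Not every call is described: the cell cycle list was called in all 11 contrasts, KO against WT at 4 weeks included.

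Serpine1 encodes PAI-1, the main inhibitor of the plasminogen activators Plat and Plau. Its locus in GRCm38 is chromosome 5, 137061504 to 137072268, on the minus strand. Counts were 41 to 258 in the 9 WT libraries and 0 to 62 in the 9 KO libraries. Mean Serpine1 was 6.57 ± 4.28 CPM (SD) in uninjured WT, 7.54 ± 2.45 at 2 weeks and 6.37 ± 4.80 at 4 weeks. In KO it was 1.02 ± 1.25, 1.41 ± 1.21 and 1.11 ± 0.458 CPM. The genotypes overlapped, since WT uninjured replicate 3 (1.96 CPM) lay below KO uninjured replicate 2 (2.42 CPM) and KO 2 weeks replicate 2 (2.72 CPM). The log2 fold change of Serpine1, KO over WT, was -2.64 ± 1.06 in uninjured tendon (adjusted p = 0.418), -2.42 ± 1.04 at 2 weeks (0.34) and -2.52 ± 1.06 at 4 weeks (0.267), none of which passed. With injury in WT, Serpine1 differed by 0.20 at 2 weeks (adjusted p = 0.936) and did not pass at 4 weeks (adjusted p = 0.986). The labels do not say which exons the allele removes, and a count per gene cannot place the KO counts on exons.

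**Figure D1:**
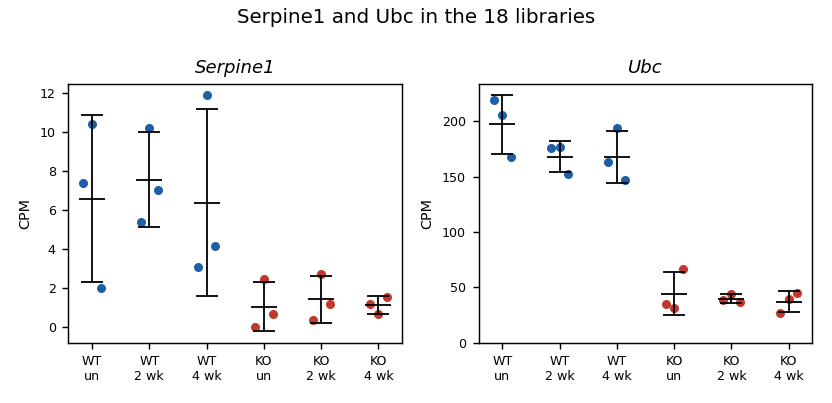
Serpine1 and Ubc in CPM (linear axis) in the 6 groups; points are libraries, the line is the mean and bars are the SD (n = 3). Serpine1 was 1.96 to 11.9 CPM in WT and 0 to 2.72 CPM in KO, while mean Ubc was 168 to 197.4 CPM in WT and 36.95 to 44.26 CPM in KO.

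The first comparison asked how WT tendon had changed 2 weeks after injury. Matrix-degrading enzymes were among the largest increases: Mmp13, a collagenase, rose from 0.395 to 1124 CPM (log2 11.46 ± 1.31, adjusted p = 0.000137), Mmp9, a gelatinase, rose by 10.91 ± 2.09 (0.00364), and Mmp10, a stromelysin, was at least 1460-fold higher. Kif2c, a kinesin of the mitotic spindle, was at least 890-fold higher, and Sapcd2, Mstn (myostatin), Neil3 (a DNA glycosylase) and Tnfsf11 (RANKL, the osteoclast differentiation factor) were at least 343-fold, 322-fold, 318-fold and 282-fold higher. Melk, a mitotic kinase, had 1 count in uninjured WT and a ratio of 1290 (95% counting interval 232 to 51100), and the chemokine Ccl17 had 2 counts and a ratio of 992 (274 to 8200). Genes that fell included Tcap, a sarcomere protein (-7.41 ± 1.87, adjusted p = 0.0275), Ibsp, bone sialoprotein (-6.34 ± 1.56, 0.0173), the nuclear receptor Rorc (-4.98 ± 0.90, 0.00259) and Cytl1, a cartilage cytokine that went from 613.4 to 20.5 CPM (-4.90 ± 1.08, 0.0089). Chodl (-6.07), Fxyd3 (-5.43), the leptin receptor Lepr (-4.97), Dlx5 (-4.74), Stk32b (-4.47) and S100a5 (-4.35) fell as well.

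Of the 50 tested cell cycle genes, 44 rose in WT at 2 weeks, and 47 rose adjusted over the list alone (adjusted p = 3.33e-38, and adjusted p = 0.256 with an estimated correlation). Among them were the mitotic kinase Aurka (adjusted p = 8.97e-06, higher in 3 of 3 injured libraries), Cenpa (4.94) and Rrm2 (3.71). Metalloproteinases and inhibitors had 17 of 37 genes up and 3 down, and 19 and 4 adjusted over the list alone (adjusted p = 3.79e-08, and adjusted p = 0.0979 with an estimated correlation). Adam12 rose by 6.99 ± 0.74. Collagens and collagen processing had 17 of 36 up, and 25 up and 2 down adjusted over the list alone (adjusted p = 8.38e-10, and adjusted p = 0.587 with an estimated correlation). Col5a3 read 3.42 ± 0.40. Matrix glycoproteins had 15 of 36 up and 1 down, and 20 and 1 adjusted over the list alone (adjusted p = 7.16e-07, and adjusted p = 0.439 with an estimated correlation). They included Cthrc1 (8.76 ± 0.73), fibronectin Fn1 (2.24 ± 0.27) and periostin, Postn (7.91 ± 0.96). Macrophage markers had 10 of 30 up, and 21 up and 1 down adjusted over the list alone (adjusted p = 7.06e-09, and adjusted p = 0.667 with an estimated correlation), among them the lysozyme Lyz2 (2.41) and the scavenger receptor Msr1 (2.27). Osteoclast markers had 3 of 13 up, and 11 adjusted over the list alone (adjusted p = 3.25e-05, and adjusted p = 0.482 with an estimated correlation), with cathepsin K, Ctsk, at 2.36 ± 0.35 and Acp5 at 5.38 ± 1.02. Cytokines and chemokines had 8 of 33 up, and 8 up and 1 down adjusted over the list alone (adjusted p = 0.000222, and adjusted p = 0.416 with an estimated correlation), with Ccl8 at 8.28 ± 0.82.

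Circadian clock genes had 12 of 18 down and 1 up in WT at 2 weeks, with the same counts adjusted over the list alone (adjusted p = 3.55e-07, and adjusted p = 0.192 with an estimated correlation). The repressor Nr1d1 read -2.10 ± 0.30 and Per3 -2.09 ± 0.31. Harvest times are not given, so injury and time of day cannot be told apart for clock genes in any comparison with uninjured libraries. Synovium and lubricating cell markers had 5 of 9 down, and 7 down and 1 up adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.638 with an estimated correlation). Htra4 read -2.76 ± 0.45 and Cd55 -2.39. Chondrocyte markers had 3 of 18 down and 1 up, and 5 and 2 adjusted over the list alone (adjusted p = 0.0305, and adjusted p = 0.724 with an estimated correlation). Tenocyte markers had 5 of 28 up and 3 down (6 and 8 adjusted over the list alone) and the list did not pass (adjusted p = 0.781), although Tnc, tenascin C, and Kera, keratocan (5.62 ± 0.80), rose. In all, 1084 genes were higher and 610 lower. The count was 954 without WT 2 weeks replicate 1, 1033 without replicate 3, 854 without WT uninjured replicate 1 and 838 without WT uninjured replicate 3. It was 53 with the summed skeletal muscle list as a covariate. The covariate was the log2 of the whole list's CPM sum, taken before TMM. Over the tested members on the TMM scale, the sum was 137 to 248 CPM in uninjured and 347 to 826 CPM in injured libraries. Tpm1 made up 74.2 to 97% of it. As these ranges do not overlap, the fit cannot part injury from that sum.

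**Figure D2:**
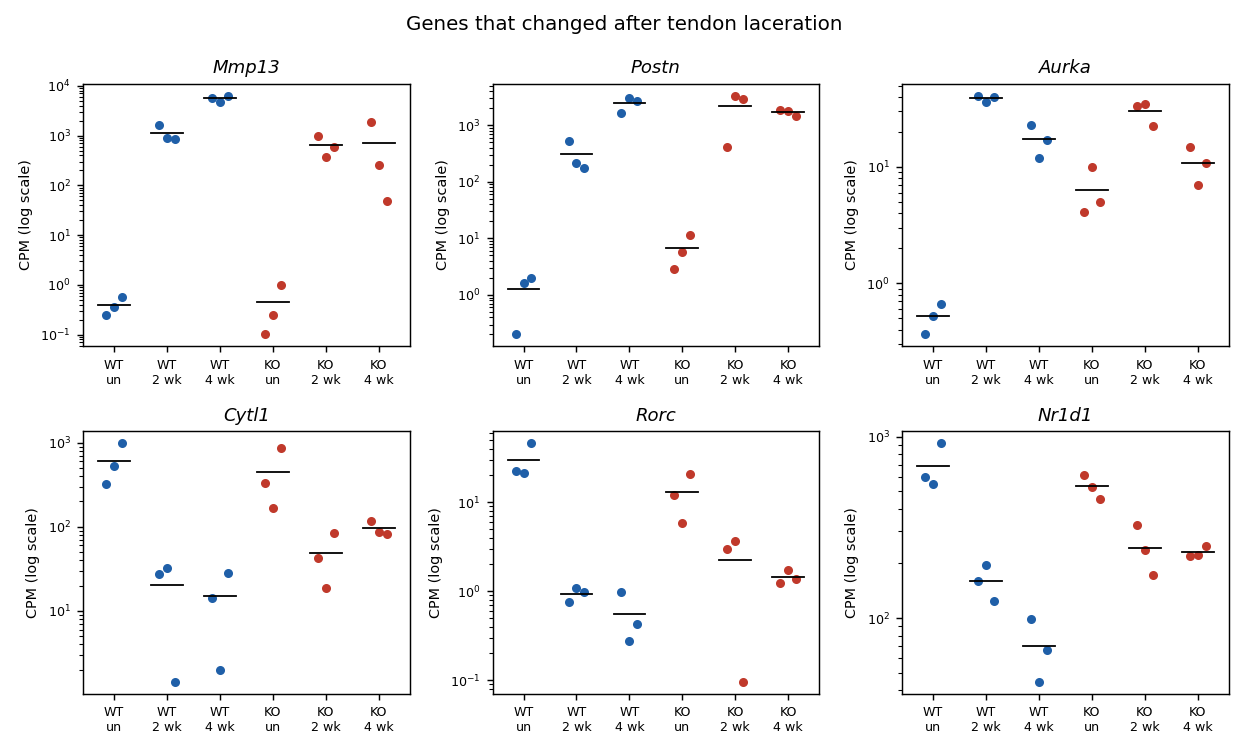
CPM (log axis) of Mmp13, Postn, Aurka, Cytl1, Rorc and Nr1d1 in the 6 groups; points are libraries and the line is the mean of 3. Mean Mmp13 was 0.395 CPM in uninjured WT and 1124 CPM at 2 weeks, while mean Cytl1 was 613.4 and 20.5 CPM.

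The second comparison asked the same of WT tendon at 4 weeks. Mmp13 reached 5641 CPM (log2 13.79 ± 1.40, adjusted p = 2.32e-05), Postn, a matrix protein of healing connective tissue, went from 1.27 to 2430 CPM (10.90 ± 1.07, 1.93e-05), and Mmp9 rose by 10.65. Mstn was at least 2000-fold higher, Mmp10 1710-fold, Tmeff1 482-fold, Prss35 450-fold, Kif2c 349-fold and Tnfsf11 311-fold, each as a lower bound, and Plekhg4 had a ratio of 2030 (692 to 9830, 3 counts in uninjured WT). Coch, cochlin, fell from 6290 to 70.9 CPM (-6.47 ± 1.74, adjusted p = 0.0209), and Frzb, a secreted Wnt antagonist, read -6.20 ± 1.05 (0.00109). Dlx5 (-5.83), Cytl1 (-5.37), the Wnt receptor Fzd9 (-5.10), Hrct1 (-4.92), Rorc and Mettl7a3 fell too. Tcap was at least 238-fold lower, and Lor, a protein of the skin's cornified layer, had 1 count at 4 weeks and a ratio of 4990 (896 to 197000, adjusted p = 0.0488). The keratinocyte list, which holds Lor, summed to 179, 1540 and 341 CPM in WT uninjured replicates 1, 2 and 3, so this baseline was uneven.

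Cell cycle genes at 4 weeks in WT had 33 of 50 up, and 42 adjusted over the list alone (adjusted p = 3.88e-20, and adjusted p = 0.482 with an estimated correlation). Aurka read 5.05 ± 0.44. Metalloproteinases and inhibitors had 20 of 37 up and 3 down, and 22 and 3 adjusted over the list alone (adjusted p = 7.69e-10, and adjusted p = 0.0955 with an estimated correlation). Mmp11 rose by 4.21 ± 0.41 and Mmp3 by 7.31. Collagens had 17 of 36 up and 2 down, and 25 and 4 adjusted over the list alone (adjusted p = 1.18e-08, and adjusted p = 0.642 with an estimated correlation). Col3a1 read 3.02 ± 0.35. Matrix glycoproteins had 20 of 36 up and 2 down, and 21 and 2 adjusted over the list alone (adjusted p = 1.08e-08, and adjusted p = 0.322 with an estimated correlation). Cthrc1 read 9.59 ± 0.76. Macrophage markers had 11 of 30 up and 2 down, and 15 and 2 adjusted over the list alone (adjusted p = 5.02e-06, and adjusted p = 0.724 with an estimated correlation). Osteoclast markers had 7 of 13 up, and 9 adjusted over the list alone (adjusted p = 5.18e-06, and adjusted p = 0.438 with an estimated correlation). Acp5 read 5.61. Clock genes had 9 of 18 down and 2 up, and 12 and 2 adjusted over the list alone (adjusted p = 3.91e-05, and adjusted p = 0.322 with an estimated correlation). Per3 read -3.10 ± 0.32 and Ciart -4.40 ± 0.58. Synovium markers had 7 of 9 down, and 7 down and 1 up adjusted over the list alone (adjusted p = 0.00118, and adjusted p = 0.634 with an estimated correlation), among them Prg4, the lubricant lubricin (-2.18 ± 0.47), and Htra4 (-3.52 ± 0.47).

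Tenocyte markers at 4 weeks in WT went both ways, 8 of 28 up and 12 down (9 and 12 adjusted over the list alone), and the list did not pass (adjusted p = 0.545; median -0.82, mean 0.04). Kera rose by 6.22 and Lum, lumican, by 3.80. The myofibroblast and TGF-beta list had 9 of 31 up and 5 down (9 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.293). Lrrc15, a marker of activated fibroblasts, rose by 9.58 ± 0.87, and Ctgf, a matricellular growth factor, read -2.84 ± 0.44. Of the 16 tested plasminogen system genes, 2 fell and 3 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.474). These were Thbd, thrombomodulin (-3.42 ± 0.33), and Serpine2, another inhibitor of plasminogen activators (-1.71 ± 0.34). In all, 1393 genes were higher and 1099 lower. The count was 1619, 1575 and 1504 without WT 4 weeks replicates 1, 2 and 3, 1547 and 1268 without WT uninjured replicates 1 and 3, and 728 with the skeletal muscle covariate.

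The third comparison asked whether WT tendon changed between 2 and 4 weeks. No gene passed in edgeR, with 1698 at an unadjusted p under 0.05, while 339 passed in DESeq2, 2321 in limma voom and 168 in edgeR with only these groups in the fit. The smallest p-values belonged to Actb, cytoplasmic actin (-1.44 ± 0.21, adjusted p = 0.0723), Actr2 (0.89 ± 0.14, 0.0916), the tubulin Tuba1b (0.0916), Ubtd2 (higher, 0.0916) and Trp53 (-0.97 ± 0.17, 0.096). Cell cycle genes had a median log2 fold change of -1.20 with no member passing alone (adjusted p = 9.9e-12, and adjusted p = 0.667 with an estimated correlation). Ribosomal protein genes had a median of -0.46 (adjusted p = 7.06e-09, and adjusted p = 0.782 with an estimated correlation), with sums of 6190, 6850 and 10900 CPM in WT 2 weeks replicates 1, 2 and 3 and 7170, 5050 and 5210 CPM at 4 weeks, so 2-week replicate 3 stood apart. Metalloproteinases had a median of 0.51 with 4 of 37 up adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.508 with an estimated correlation), and matrix glycoproteins 0.52 with 2 up and 1 down adjusted over the list alone (adjusted p = 0.0041, and adjusted p = 0.695 with an estimated correlation). Without WT 4 weeks replicate 1, 4 genes passed, and without WT 2 weeks replicate 1, 1 gene did.

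In KO tendon the same questions were asked against KO uninjured libraries, which differed in composition. Globin genes took 21.2% of the counts in KO uninjured replicate 1, 3.48% in replicate 2 and 0.0049% in replicate 3, against at most 0.0113% in uninjured WT. The summed keratinocyte list was 50200 CPM in KO uninjured replicate 2, 158 and 186 CPM in replicates 1 and 3, and 179, 1540 and 341 CPM in uninjured WT. Among the largest decreases in KO at 2 weeks were genes of the keratinocyte and erythroid lists: Krt14, a keratin of the basal epidermis (-14.04 ± 3.79, adjusted p = 0.0373), went from 1389 to 0.0759 CPM, Alas2, the first enzyme of heme synthesis in red cells, read -12.76 ± 2.52 (0.00617), and Hba-a1, an alpha globin, went from 25560 to 8.67 CPM (-11.53 ± 2.92, 0.0218). Hba-a1 and Hba-a2 are near-identical copies, so their reads cannot be fully told apart. Dsp (desmoplakin), also on the keratinocyte list, fell too. Of genes on neither list, Ly6d fell by 13.80, Tuba8, Grhl1, Cldn23 and Gp9 were at least 1410-fold, 1140-fold, 570-fold and 470-fold lower, and Rab25 had a ratio of 3900 (1080 to 32200, 2 counts). Without KO uninjured replicates 1 and 2, a fit added after the data were seen that keeps 1 KO uninjured library and takes the spread from the other groups, 778 genes were called at 2 weeks, 540 of them among the 1818 called with all libraries.

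Matrix and matrix-degrading genes were among the largest increases in KO at 2 weeks. Mmp10 was at least 496-fold higher, Mmp13 rose from 0.443 to 643.9 CPM (log2 10.47 ± 1.29, adjusted p = 0.000297), Cthrc1, a secreted collagen-associated protein, rose by 9.14 ± 0.75 (1.36e-05), and Postn rose by 8.36 ± 0.97 (0.000216). Sfrp2, a secreted Wnt modulator, rose by 8.22, Tspan11 and Il1rl1, the interleukin 33 receptor, by 7.49 each, Tnfsf11 and Iigp1 were at least 140-fold and 132-fold higher, and S1pr3, a receptor of sphingosine 1-phosphate, had a ratio of 330 (91.2 to 2730). Matrix glycoproteins had 17 of 36 up and 1 down, and 23 and 3 adjusted over the list alone (adjusted p = 2.66e-09, and adjusted p = 0.322 with an estimated correlation). Collagens had 18 of 36 up and 1 down, and 23 and 4 adjusted over the list alone (adjusted p = 3.36e-09, and adjusted p = 0.623 with an estimated correlation). Col5a1 read 2.77. Metalloproteinases had 17 of 37 up and 2 down, and 18 and 3 adjusted over the list alone (adjusted p = 9.73e-09, and adjusted p = 0.0956 with an estimated correlation). Mmp23 read 4.12 ± 0.41. Cell cycle genes had 15 of 50 up, and 29 adjusted over the list alone (adjusted p = 7.27e-15, and adjusted p = 0.601 with an estimated correlation). Aurka read 2.24 ± 0.38. Macrophage markers had 10 of 30 up and 1 down, and 12 and 1 adjusted over the list alone (adjusted p = 1.17e-06, and adjusted p = 0.7 with an estimated correlation).

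Clock genes in KO at 2 weeks had 10 of 18 down, and 14 adjusted over the list alone (adjusted p = 6.79e-07, and adjusted p = 0.192 with an estimated correlation). Per1 read -2.77 ± 0.48. Immediate early genes, which respond fast to stimuli, had 7 of 24 down, and 17 adjusted over the list alone (adjusted p = 2.2e-06, and adjusted p = 0.667 with an estimated correlation), with the transcription factor Klf4 at -2.03 ± 0.40. Keratinocyte markers had 10 of 15 down, and 15 adjusted over the list alone (adjusted p = 0.000824, and adjusted p = 0.77 with an estimated correlation), and erythroid genes had 5 of 8 down both ways, over all genes and adjusted over the list alone (adjusted p = 0.00717, and adjusted p = 0.724 with an estimated correlation). In all, 862 genes were higher and 956 lower. The count was 926 without KO 2 weeks replicate 2, 1087 without replicate 3, 256 with only these groups in the fit and 1029 in limma voom, and no gene passed in edgeR with the skeletal muscle covariate.

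At 4 weeks in KO tendon, Mmp13 was 720.9 CPM (log2 10.63 ± 1.29, adjusted p = 0.000293), Cthrc1 had risen by 8.25 ± 0.73 (5.1e-05), Postn by 7.98 ± 0.95 (0.00029) and Il1rl1 by 7.06, and Plekhg4 was at least 159-fold higher. S1pr3, Mstn, Slc6a2 (the noradrenaline transporter), Crocc2 and Htr2b (a serotonin receptor) had ratios of 666 (184 to 5510), 618 (110 to 24400), 505 (90.2 to 20000), 431 (77 to 17100) and 316 (87.2 to 2620). Decreases were led by genes high in KO uninjured replicates 1 or 2, the libraries with 21.2% globin counts and 50200 CPM of keratinocyte genes: Ly6g6c and Gp9 were at least 6310-fold and 290-fold lower, and Mpl, the thrombopoietin receptor, had no count at 4 weeks. Lor read -11.31 (adjusted p = 0.0443) and Slurp2 -10.54, and Dsp fell. Pdzk1ip1, Tuba8, Grhl1 and Aloxe3 were lower with ratios of 4100 (735 to 162000), 2610 (468 to 103000), 2100 (377 to 83200) and 979 (335 to 4750). Collagens had 21 of 36 up, and 26 up and 2 down adjusted over the list alone (adjusted p = 1.36e-11, and adjusted p = 0.509 with an estimated correlation), with the crosslinking enzyme Loxl1 at 4.05 ± 0.57. Matrix glycoproteins had 19 of 36 up and 2 down, and 24 and 2 adjusted over the list alone (adjusted p = 2.62e-11, and adjusted p = 0.224 with an estimated correlation). Metalloproteinases had 13 of 37 up and 1 down, and 16 and 2 adjusted over the list alone (adjusted p = 1.7e-09, and adjusted p = 0.0955 with an estimated correlation), with Mmp2, a gelatinase, at 3.92 ± 0.48.

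Ribosomal protein genes in KO at 4 weeks had 18 of 50 down, and 43 adjusted over the list alone (adjusted p = 2e-16, and adjusted p = 0.695 with an estimated correlation), with Rps14 at -1.29; their summed level was 7430, 13200 and 8080 CPM in KO uninjured replicates 1, 2 and 3 and 6100, 5390 and 4710 CPM at 4 weeks. Cell cycle genes had 4 of 50 up, and 5 adjusted over the list alone (adjusted p = 4.89e-09, and adjusted p = 0.702 with an estimated correlation), with the replication factor Mcm3 at 1.39 ± 0.26. Clock genes had 6 of 18 down, and 9 adjusted over the list alone (adjusted p = 6.73e-05, and adjusted p = 0.322 with an estimated correlation). Cry2 read -1.76. In the plasminogen system, 3 of 16 genes fell (Thbd, tissue factor F3 at -3.13 and S100a10 at -0.76), with 5 down and 1 up adjusted over the list alone, and the list did not pass (adjusted p = 0.564). In all, 660 genes were higher and 537 lower. The count was 686, 643 and 540 without KO 4 weeks replicates 1, 2 and 3, 401 without KO uninjured replicates 1 and 2 (253 of them among the 1197), 103 with only these groups in the fit and 1 with the skeletal muscle covariate.

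Between 2 and 4 weeks in KO tendon, 3 genes passed, all higher at 4 weeks: Rev1, a translesion DNA polymerase (1.39 ± 0.20), Man2b2, a lysosomal mannosidase (1.31 ± 0.19), and Tacc2 (0.89 ± 0.13), each with adjusted p = 0.0207. All 3 passed without KO 2 weeks replicate 3 and none passed without any other library of the 2 groups, with adjusted p of 0.0662 (KO 4 weeks replicate 3) to 0.161 (KO 2 weeks replicate 2). Lbr, the lamin B receptor (1.31, adjusted p = 0.0595), and Mfi2 (at least 573-fold higher, 0.0697) had the next smallest p-values and did not pass. Ribosomal protein genes had a median of -0.62 (adjusted p = 5.66e-19, and adjusted p = 0.667 with an estimated correlation), cell cycle genes -0.87 (adjusted p = 6.62e-05, and adjusted p = 0.783 with an estimated correlation) and interferon response genes -1.04 (adjusted p = 0.00126, and adjusted p = 0.773 with an estimated correlation), with no member passing over all genes or adjusted over the list alone. The interferon list summed to 909, 237 and 361 CPM in KO 2 weeks replicates 1, 2 and 3. Without KO 2 weeks replicate 3, 13 genes passed; without any other single library of these groups, none passed in edgeR, where 2057 had an unadjusted p under 0.05 in the full fit, while DESeq2 called 308.

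The responses of the genotypes were compared across genes, which are not independent replicates. At 2 weeks the log2 fold changes of WT and KO had Pearson r = 0.446 and Spearman rho = 0.436 over 16844 genes, and r = 0.736 over the 9332 genes with an average of at least 10 CPM. Of the genes called, 497 were higher in both (55.5 if independent), 282 lower in both (34.6) and 0 opposite, and 1609 of the 1694 WT calls (95%) had the same sign in KO. At 4 weeks r was 0.498 and rho 0.416 (r = 0.75 at 10 CPM or more), with 410 higher in both (54.6 if independent), 220 lower in both (35) and 8 opposite, and 2170 of 2492 WT calls (87.1%) had the same sign. Mmp13, Cthrc1 and Postn rose in both genotypes at both times, but not to like levels. At 4 weeks mean Mmp13 was 5640 CPM in WT and 721 CPM in KO. The metalloproteinase list, which holds Mmp13, summed to 18000, 9940 and 7000 CPM in KO 4 weeks replicates 1, 2 and 3. In WT 4 weeks replicates 1, 2 and 3 it summed to 25200, 21500 and 22300 CPM.

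KO and WT were next compared in uninjured tendon, which asks how the 2 groups differed without injury. Of 4 genes called, 2 were lower in KO and lie on chromosome 5, as Serpine1 does: Ubc, polyubiquitin, was 44.26 ± 19.6 CPM (SD) in KO and 197.4 ± 26.6 in WT (log2 -2.16 ± 0.26, adjusted p = 0.0043), and Gbas read -1.36 ± 0.20 (0.0217). Aurka was higher in KO, at 6.35 CPM against 0.519 (3.61 ± 0.42, 0.0043), in 3 of 3 libraries, as was Napsa, the aspartic protease napsin A (5.40 ± 0.82, 0.028). Il2rg, the common chain of several interleukin receptors, came next and did not pass (2.74 ± 0.46, 0.0755). Cell cycle genes had a median of 2.04, with 1 of 50 up over all genes and 23 up and 1 down adjusted over the list alone (adjusted p = 6.86e-11, and adjusted p = 0.667 with an estimated correlation). Their sum was 504, 975 and 386 CPM in KO replicates 1, 2 and 3 and 391 to 409 CPM in WT. T and NK cell genes had 9 of 15 up adjusted over the list alone (adjusted p = 7.06e-09, and adjusted p = 0.416 with an estimated correlation; sums of 176, 42.5 and 5.14 CPM in KO replicates 1, 2 and 3, at most 3.92 in WT). B and plasma cell genes had 8 of 10 up adjusted over the list alone (adjusted p = 5.31e-07, and adjusted p = 0.482 with an estimated correlation). Their sum was 1250, 609 and 591 CPM in KO replicates 1, 2 and 3 and 545, 594 and 565 CPM in WT. Erythroid genes had 6 of 8 up (adjusted p = 1.04e-06, and adjusted p = 0.477 with an estimated correlation) and keratinocyte genes 11 of 15, adjusted in the same way (adjusted p = 0.000479, and adjusted p = 0.77 with an estimated correlation). None of these passed over all genes. Ubc and Aurka passed with each single library left out in turn. With only these groups in the fit no gene passed in edgeR, where 814 had an unadjusted p under 0.05. Limma voom called 2 genes, 1 of them among the 4. Without KO uninjured replicates 1 and 2 together Ubc had adjusted p = 0.0929, Gbas 0.099 and Napsa 0.263. Gbas had adjusted p = 0.078 without KO uninjured replicate 2 and 0.0951 and 0.15 without WT uninjured replicates 1 and 3, where Napsa had 0.0605, 0.116 and 0.266. The count of 4 became 22 without KO uninjured replicate 1, 134 without replicate 3, 15 without WT uninjured replicate 2 and 12 without KO uninjured replicates 1 and 2; DESeq2 called 342 genes. In each genotype 2 of the uninjured libraries share a title number. With these summed, 6 genes passed, 2 of them among the 4: Ubc (adjusted p = 0.0459) and Aurka (0.0176) were kept, and Gbas and Napsa (0.105 each) were lost.

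At 2 weeks after injury, 2 genes differed between KO and WT, both lower in KO. Ubc was 39.91 ± 3.78 CPM (SD) in KO and 168.2 ± 13.9 in WT (adjusted p = 0.0105), and Lbr read -1.62 ± 0.21 (0.0105), each with every KO library below every WT library. Ubc had adjusted p = 0.0672 and 0.0819 without KO 2 weeks replicates 1 and 2 and 0.127 and 0.132 without WT 2 weeks replicates 1 and 2, and Lbr had 0.0672, 0.12, 0.127 and 0.156. Tcf7l1, a Wnt pathway repressor (2.10 ± 0.33, adjusted p = 0.0512), Cdh23 (0.0512) and the helicase Recql5 (-2.88 ± 0.48, 0.0622) came next and did not pass. Interferon response genes had 9 of 31 up in KO adjusted over the list alone and none over all genes (median 1.59, adjusted p = 1.13e-11, and adjusted p = 0.508 with an estimated correlation). Their sum was 909, 237 and 361 CPM in KO replicates 1, 2 and 3 and 141 to 178 CPM in WT. Endothelium markers had a median of 4.07 (4.01 with groups at 0 set to 3 counts), with none of 25 passing over all genes or adjusted over the list alone (adjusted p = 3.15e-07, and adjusted p = 0.707 with an estimated correlation), and adipocyte markers had 8 of 18 up adjusted over the list alone (adjusted p = 5.31e-07, and adjusted p = 0.573 with an estimated correlation). Sums were 829, 1690 and 1690 CPM for endothelium and 384, 920 and 1620 CPM for adipocytes in KO replicates 1, 2 and 3. In WT they were 1030, 1180 and 953 CPM and 428, 458 and 296 CPM, so KO replicate 1 was below every WT library for endothelium and within the WT range for adipocytes. Cell cycle genes had 7 of 50 down adjusted over the list alone (median -0.65, adjusted p = 8.48e-06, and adjusted p = 0.77 with an estimated correlation). The count of 2 became 7 without KO 2 weeks replicate 3 and 46 without WT 2 weeks replicate 3, while none passed in edgeR without any other single library (2211 at an unadjusted p under 0.05 in the full fit, 414 called by DESeq2 and 742 by limma voom).

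At 4 weeks after injury, 109 genes were higher and 111 lower in KO. Prg4, lubricin, the lubricant of tendon and joint surfaces, was 12910 ± 5431 CPM (SD) in KO and 1925 ± 963 in WT (log2 2.75 ± 0.48, adjusted p = 0.0144). All 3 KO libraries lay above all 3 WT libraries, which the naming rule asked for. Other genes higher in KO were Susd5 (5.48 ± 1.01, 0.0179), Aldh1a2, which makes retinoic acid (4.39 ± 0.68, 0.00756), Vsig4, a complement receptor of resident macrophages (4.26 ± 0.92, 0.0351), Frzb (4.16 ± 0.98, 0.0487), Ntrk2 (2.83 ± 0.62) and the protease Htra4 (2.73 ± 0.45, 0.0117). Lower in KO were Thbs2, thrombospondin 2, a matrix protein (578.6 against 2695 CPM, -2.22 ± 0.42, 0.02), Itga11, a collagen receptor chain (-2.02 ± 0.45, 0.0396), Plat, tissue plasminogen activator (258.1 against 976.8 CPM, -1.92 ± 0.34, 0.015), Pxdn, which crosslinks collagen IV (-1.90 ± 0.30, 0.00838), Wnt9a (-2.23 ± 0.51, 0.0431), Ubc (-2.19 ± 0.26, 0.00671), Serinc5 (-2.08) and Zfp354c (-1.98). Dnm3os, a noncoding transcript antisense to Dnm3, also read lower (-2.54 ± 0.35, 0.00749), with the strand of its reads unmarked. Ubc passed with each single library left out in turn, while Prg4 had adjusted p = 0.0776 and 0.053 without KO 4 weeks replicates 2 and 3 and 0.0766 and 0.117 without WT 4 weeks replicates 2 and 3. In the same fits Thbs2 had 0.113, 0.0843, 0.0762 and 0.0922 and Plat 0.0753, 0.0819, 0.0523 and 0.0822.

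Of the clock genes, 5 of 18 were up and 1 down in KO at 4 weeks, and 6 and 2 adjusted over the list alone (adjusted p = 0.0293, and adjusted p = 0.667 with an estimated correlation). Per3 (2.43 ± 0.31, adjusted p = 0.00671), Per1 (2.91 ± 0.49, 0.0119), Nr1d1 (1.72 ± 0.30, 0.0137), Ciart (3.06 ± 0.55, 0.0162) and Dbp (62.7 against 9.68 CPM, 0.0251) were higher, and Arntl, the activator that drives them, was 33.57 CPM in KO against 127.5 CPM in WT (-1.92 ± 0.41, 0.0331). Per3 passed with each single library left out in turn, while Arntl had adjusted p = 0.067 to 0.15 without each library but KO 4 weeks replicate 1. Synovium and lubricating cell markers had 2 of 9 up, and 6 adjusted over the list alone (adjusted p = 0.000156, and adjusted p = 0.509 with an estimated correlation). Both called members, Prg4 and Htra4, also stand in the tenocyte list. Tenocyte markers had 2 of 28 up, and 3 up and 3 down adjusted over the list alone, and the list did not pass (adjusted p = 0.778; median 0.08, test direction down). The myofibroblast and TGF-beta list had 1 of 31 up (Ctgf, 2.54 ± 0.44) and 3 down, and 7 and 5 adjusted over the list alone, and did not pass (adjusted p = 0.928). Those down were the TGF-beta receptor Tgfbr1 (-1.75 ± 0.30), the integrin Itgav (-0.97 ± 0.21) and Skil (-1.56 ± 0.35). The plasminogen system had 1 of 16 down (Plat), and 3 up and 1 down adjusted over the list alone, and did not pass (adjusted p = 0.647). Matrix glycoproteins had 1 of 36 up and 2 down, and 2 and 3 adjusted over the list alone, and did not pass (adjusted p = 0.193).

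Some lists of other cell types were called at 4 weeks with the preset correlation only. Endothelium markers had a median of 1.57, with none of 25 passing over all genes or adjusted over the list alone (adjusted p = 0.000404, and adjusted p = 0.782 with an estimated correlation). Their sum was 1530, 2250 and 3170 CPM in KO replicates 1, 2 and 3 and 869, 1640 and 998 CPM in WT. Schwann cell and nerve genes had 1 of 19 up (S100b, 2.49 ± 0.50), and 4 adjusted over the list alone (adjusted p = 0.000184, and adjusted p = 0.74 with an estimated correlation), with sums of 694, 979 and 2710 CPM in KO replicates 1, 2 and 3 and 314, 497 and 479 CPM in WT. Mast cell genes had 5 of 9 up adjusted over the list alone and none over all genes (median 6.47, or 5.99 with groups at 0 set to 3 counts, adjusted p = 0.00152, and adjusted p = 0.724 with an estimated correlation), with sums of 0.714, 88.5 and 71.8 CPM in KO replicates 1, 2 and 3 and at most 8.58 CPM in WT libraries. Mitochondrially encoded transcripts had 1 of 10 up (mt-Nd5, 1.46 ± 0.27), and 7 adjusted over the list alone (adjusted p = 7.74e-06, and adjusted p = 0.667 with an estimated correlation). The 220 calls became 426, 10 and 34 without KO 4 weeks replicates 1, 2 and 3, and 128, 28 and 23 without WT 4 weeks replicates 1, 2 and 3. They became 91 with only these groups in the fit and 86 with the summed endothelium list as a covariate.

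**Figure D3:**
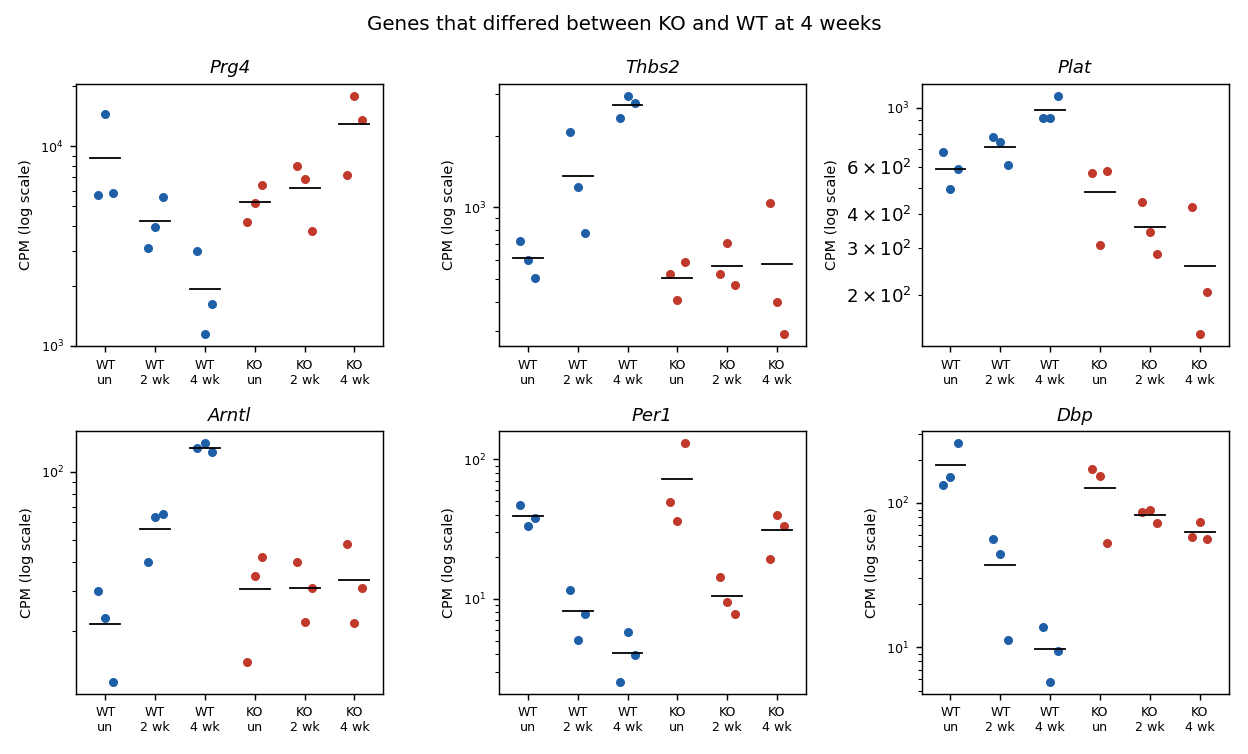
CPM (log axis) of Prg4, Thbs2, Plat, Arntl, Per1 and Dbp in the 6 groups; points are libraries and the line is the mean of 3. At 4 weeks mean Prg4 was 12910 CPM in KO and 1925 CPM in WT, and mean Arntl was 33.57 and 127.5 CPM.

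Whether the genotypes differed in their response to injury was tested directly. In the 2-week response 1 gene differed: Aurka rose less in KO (-3.98 ± 0.55, adjusted p = 0.037), from 6.35 CPM in uninjured KO and 0.519 CPM in uninjured WT to 30.2 and 39.2 CPM. Its adjusted p was 0.0512 to 0.185 when any one of the 2-week libraries, the WT uninjured libraries or KO uninjured replicate 2 was left out. In the 4-week response 12 genes were higher and 11 lower in KO relative to WT. They included Aurka (-4.28 ± 0.55, adjusted p = 0.0169), Atoh8, a transcription factor (3.10 ± 0.44, 0.0223), Anxa11 (2.17 ± 0.32, 0.0223), the membrane-shaping protein Ehd2 (2.20 ± 0.33, 0.0223), Hspb7 (2.68 ± 0.42, 0.0256), Il2rg (-3.86 ± 0.62, 0.0354) and Htra4 (3.41 ± 0.62, 0.0445). Per3 also responded differently (0.0235). It had adjusted p = 0.0575 and 0.065 without KO 4 weeks replicates 2 and 3, 0.0617, 0.08 and 0.0821 without WT 4 weeks replicates 1, 2 and 3, and 0.0658 without WT uninjured replicate 3. At 4 weeks Aurka had adjusted p = 0.0562 without KO 4 weeks replicate 3 and 0.0561 without WT uninjured replicate 3. Prg4 differed by 3.47 ± 0.66 and did not pass (adjusted p = 0.058). Cell cycle genes had 1 of 50 lower at both times over all genes, and 30 lower at 2 weeks (adjusted p = 2.71e-16, and adjusted p = 0.573 with an estimated correlation) and 22 lower at 4 weeks (adjusted p = 2.36e-08, and adjusted p = 0.724 with an estimated correlation) adjusted over the list alone, with sums of 504, 975 and 386 CPM in uninjured KO replicates 1, 2 and 3. The 1 call at 2 weeks became 4 without KO uninjured replicate 1, 30 without replicate 3, 10 without replicates 1 and 2 and none in edgeR with only these groups in the fit (1833 at an unadjusted p under 0.05 in the full fit, 250 called by DESeq2). The 23 calls at 4 weeks became 91, 5 and 0 without KO 4 weeks replicates 1, 2 and 3, and 3, 2 and 2 without WT 4 weeks replicates 1, 2 and 3. They became 58, 13 and 119 without KO uninjured replicates 1, 2 and 3, 3 and 0 without WT uninjured replicates 1 and 3, and 0 in edgeR with only these groups in the fit. With same-numbered uninjured libraries summed 17 passed, 12 of them among the 23. In this comparison 2449 had an unadjusted p under 0.05 in the full fit, DESeq2 called 702 and limma voom 260.

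The strain name, B6.129S2-Serpine1tm1Mlg/J, gives the targeted allele another strain of origin than its C57BL/6 background, so genes near Serpine1 were compared with genes elsewhere. Within 10 Mb of Serpine1, 7 of 262 genes were called between KO and WT at 4 weeks, against 212 of 16347 elsewhere (odds ratio 2.09, 95% interval 0.821 to 4.44, Fisher's exact p = 0.0891, adjusted 0.178). The same test gave 1 of 262 in uninjured tendon (exact p = 0.0616, adjusted 0.148) and 0 of 262 at 2 weeks (exact p = 1), where edgeR called 2 genes in all, 2211 had an unadjusted p under 0.05, DESeq2 called 414 and limma voom 742. With a window of 20 Mb it gave 2 of 445 in uninjured tendon (exact p = 0.00415, adjusted 0.0474), 1 of 445 at 2 weeks (exact p = 0.0529, adjusted 0.148) and 12 of 445 at 4 weeks (exact p = 0.0178, adjusted 0.0712). With a window of 5 Mb it gave 4 of 153 at 4 weeks (exact p = 0.144, adjusted 0.216). That window held 0 of the few genes called in uninjured tendon or at 2 weeks. In the effect averaged over the 3 states, which was added after the data were seen, 145 genes were higher and 181 lower in KO, Serpine1 passed (adjusted p = 0.0456), and the 6 genes with the smallest p were all on chromosome 5, which held 7.05% of the genes. These were Ubc (-2.14 ± 0.15, adjusted p = 4.94e-06, 9 KO libraries and 9 WT libraries), Gbas (-1.22 ± 0.11, 9.85e-05), Agfg2 (-1.10 ± 0.12, 0.000453), Pan3, a subunit of a poly(A) nuclease (1.34 ± 0.16, 0.00172), Kdelr2, a retrieval receptor of the endoplasmic reticulum (0.00172), and Tmed2 (-0.84 ± 0.11, 0.00301). Each was separated by genotype in all 3 states. The gene ranked 7 by p, Usp47, lies on chromosome 7, and Arpc1a on chromosome 5 was ranked 22. In the averaged effect 5 of 153 genes within 5 Mb of Serpine1 were called (Fisher's exact p = 0.227, adjusted 0.303). Within 10 Mb 9 of 262 were called (exact p = 0.106, adjusted 0.182). Within 20 Mb 17 of 445 were called, against 306 of 16164 elsewhere (exact p = 0.0079, adjusted 0.0474). Ubc (125385965 to 125390202, minus strand) overlaps Gm10382 (125389322 to 125390554, plus strand; -4.20 ± 0.96), and without strand their reads cannot be told apart in the overlap.

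**Figure D4:**
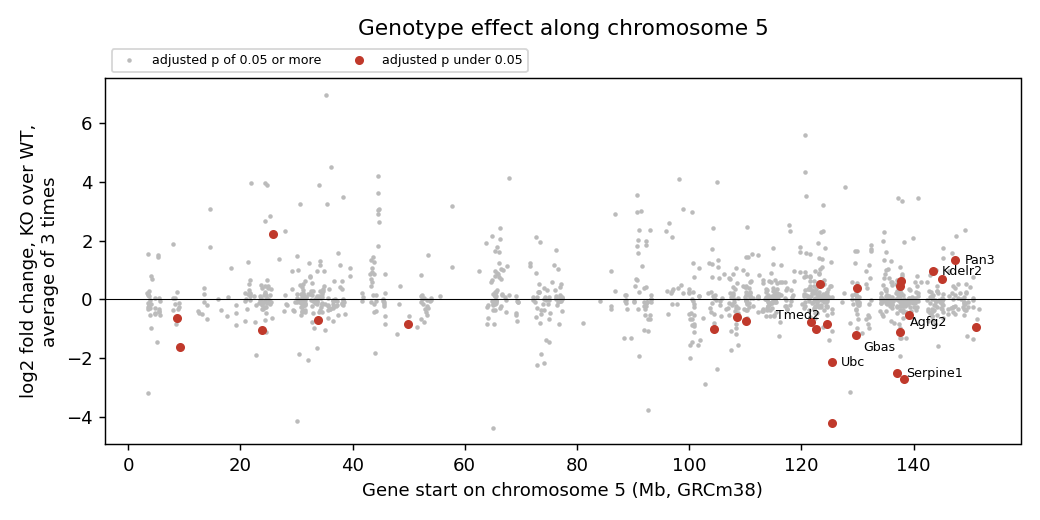
Log2 fold change of KO over WT averaged over the 3 states (vertical axis) against gene start on chromosome 5 in Mb of GRCm38 (horizontal axis); each point is a tested gene, red where the adjusted p was under 0.05. Named points include Ubc at -2.14, Gbas at -1.22 and Pan3 at 1.34.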

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

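The tests of blood and skin transcripts, of genes near Serpine1, of vessel cells and of the clock, the fits without KO uninjured replicates 1 and 2 or with the endothelium covariate, and the averaged genotype effect were chosen after the result was seen; the splits of the libraries were planned, but they were run first in fits of only the groups compared and then, after those values were seen, in the fit of all 18 libraries.

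A difference between WT and KO in the response to injury stood out in 1 gene at 2 weeks, Aurka (log2 -3.98), and in 23 genes at 4 weeks. Higher in KO relative to WT at 4 weeks were Htra4 (3.41), Atoh8 (3.10), the ion channel Trpv4 (2.84), the clock gene Per3 (2.83), Hspb7 (2.68), the matrix protein Tnxb (2.43), Cystm1 (2.28), Ehd2 (2.20), Palm (2.20) and Anxa11 (2.17). Lower were Aurka (-4.28), Il2rg (-3.86), the myeloid lectin Clec4d (-3.59), Dnm3os (-2.81), Rasa2 (-1.68), Sub1 (-1.66), Erbin (-1.52), Ext1 (-1.39), an enzyme of heparan sulfate synthesis, Tceb1 (-1.16) and Arpp19 (-1.04). The named rule took 20 of the 23 genes, and their adjusted p ran from 0.0169 to 0.048. The 23 calls became 119 without KO uninjured replicate 3 and 0 without KO 4 weeks replicate 3 or WT uninjured replicate 3.

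Gene lists were also called in the difference in response at 2 weeks, none of them with an estimated correlation, each given as the median log2 difference, its adjusted p and its adjusted p with an estimated correlation. Lower in KO relative to WT were the cell cycle (-2.81, 2.71e-16, 0.573), T and NK cells (-4.09, 0.0104, 0.762), B and plasma cells (-6.04, 0.00396, 0.724), erythroid cells (-6.36, 0.0326, 0.77), oxidative phosphorylation (-0.24, 0.0104, 0.852) and ribosomal proteins (-0.62, 3.55e-07, 0.804). Higher were mast cells (6.30, 0.0139, 0.773), the interferon response (1.54, 1.97e-07, 0.667), endothelium (3.94, 0.00095, 0.788), pericytes and smooth muscle (3.63, 0.0139, 0.77) and adipocytes (4.71, 5e-05, 0.667). With groups at 0 set to 3 counts the medians were -3.01 for T and NK cells, -6.76 for B and plasma cells, 4.19 for mast cells, 1.22 for the interferon response and 3.66 for endothelium.

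At 4 weeks the same measures were lower for the cell cycle (-2.78, 2.36e-08, 0.724), T and NK cells (-4.08, 0.00717, 0.746), B and plasma cells (-8.62, 0.00679, 0.746), osteoclasts (-0.67, 0.0379, 0.762), erythroid cells (-7.92, 0.0241, 0.77), oxidative phosphorylation (-0.33, 0.000158, 0.783), ribosomal proteins (-0.76, 1.71e-11, 0.762) and p53 targets and apoptosis (-0.58, 0.00422, 0.439). They were higher for mast cells (7.10, 0.0419, 0.813), the interferon response (0.83, 0.015, 0.82), endothelium (1.16, 0.0365, 0.878), adipocytes (3.24, 0.00288, 0.756), Schwann cells and nerve (2.75, 0.0273, 0.82), synovium and lubricating cells (1.74, 0.000547, 0.587) and fatty acid oxidation (0.30, 0.0248, 0.642). With groups at 0 set to 3 counts the medians were -3.33 for T and NK cells, -5.31 for B and plasma cells, -7.73 for erythroid cells, 3.63 for mast cells, 0.67 for the interferon response, 2.79 for adipocytes and 2.65 for Schwann cells and nerve. The adipocyte sum was 335, 842 and 707 CPM in KO 4 weeks replicates 1, 2 and 3 and 346, 446 and 299 CPM in WT, so KO replicate 1 lay within the WT range.

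Other splits of the same libraries were counted in the fit of all 18. For the differences in response, 8 of 100 splits, the real one included, gave at least 1 gene at 2 weeks (highest other split 6), so chance was not excluded there. The split with 6 genes kept the libraries of each genotype together and only swapped the sides at 2 weeks. It thus measured the genotype difference of both states together, not a random grouping. At 4 weeks 2 of 100 splits gave at least 23 genes, a share under 0.05, but the other one gave 78 genes, several times the real count, which points to a structure of the samples. That split set KO 4 weeks replicates 2 and 3 and WT 4 weeks replicate 2 (-74.7, -109.9 and -17 on the second principal component) against KO 4 weeks replicate 1 and WT 4 weeks replicates 1 and 3 (45.5, 80.1 and 56.3). It also set KO uninjured replicate 1 and WT uninjured replicates 1 and 3 (9.7, 43.7 and 22.2) against the other uninjured libraries (-34.4, -3.4 and -20.3). What parts these libraries was not tested. In fits of only the groups compared, the real counts of both differences were 0 in edgeR, with 1833 and 2449 genes at an unadjusted p under 0.05 in the full fit and 250 and 702 called by DESeq2, and other splits reached 4 and 91. The split with 4 was again the one with the genotypes swapped at 2 weeks. The split with 91 grouped the libraries as the one with 78 did. For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 1694 and 0 for WT at 2 weeks, 2492 and 0 for WT at 4 weeks, 1818 and 5 for KO at 2 weeks, 1197 and 4 for KO at 4 weeks, and 3 and 1 for KO 4 against 2 weeks. They were 4 and 2 for KO against WT in uninjured tendon, 2 and 1 at 2 weeks, and 220 and 0 at 4 weeks; for WT 4 against 2 weeks all 10 splits gave as many as the real 0 genes in edgeR, where 1698 had an unadjusted p under 0.05, DESeq2 called 339 and limma voom 2321. In fits of only the groups compared, KO against WT at 4 weeks gave 91 and another split 197.

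The first pattern weighed was the blood, skin and cell cycle transcripts of uninjured KO libraries, on which the lists lower in KO response rest in part. All 15 tested keratinocyte markers were highest in KO uninjured replicate 2 (Krt14 at 4159 CPM against 0 to 16.5 CPM in uninjured WT), and 6 of 8 erythroid markers were highest in replicate 1 (Hba-a1 at 67510 CPM), so skin cells in replicate 2 and blood cells in replicate 1 are a candidate source; 10 of the 15 and 4 of the 8 markers had 3 counts or more in every uninjured WT library, none stands in another list, and the labels name no sort that would remove such cells. Without both libraries the cell cycle median between uninjured KO and WT went from 2.04 to 0.13 (0.26 with groups at 0 set to 3 counts), but this decides nothing, since the 2 libraries left out are those with the highest cell cycle sums (504 and 975 CPM against 386 CPM in replicate 3 and 391 to 409 CPM in WT). That fit rests on KO uninjured replicate 3 alone, with the spread taken from the other groups, and in that library Aurka was still 4.98 CPM against 0.365 to 0.667 CPM in WT. For the cell cycle genes, cells of blood and skin and a difference in uninjured KO tendon itself cannot be told apart.

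The second pattern was the genes on chromosome 5 that differed at every time. Of the 445 genes within 20 Mb of Serpine1, 10 (2.25%) were separated by genotype in the same direction in all 3 states, against 49 of 16164 elsewhere (0.303%; odds ratio 7.56, 3.39 to 15.2, Fisher's exact p = 3.34e-06). Ubc and Gm10382, which overlap, are 2 of the 10. This test counts the genes in which the pattern was seen, so it does not decide whether flanking sequence of the allele's strain of origin, carried along in B6.129S2-Serpine1tm1Mlg/J mice, is behind it, and that stays open. Reads of that strain's alleles that fail to align cannot account for the 7 of 17 called genes near Serpine1 that were higher in KO. For the 10 that were lower, such loss and a real decrease cannot be told apart, since no reads were used here to look at variant positions. An effect of the lost PAI-1 on these genes stays open too, as the same animals carry both.

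The third pattern was the difference between KO and WT at 4 weeks. A larger share of vessel cells was looked at with the summed endothelium list as a covariate. Of the 25 genes in that list, 9 had 3 counts or more in every uninjured WT library, and 2 stand in another list. With this covariate the log2 fold changes of the 220 called genes kept a median ratio of 0.96. Only 54 of them stayed called, as their SE grew by a median ratio of 1.2 and the count fell to 86. These values do not decide whether vessel cells are behind the difference. The slope on the sum comes from differences between libraries within groups, and the 220 genes were picked by their call. Of 15 clock genes, 13 had a log2 fold change with the sign that a shift of phase would give, called or not. The direction of shift with more genes was the one counted, so a majority was certain. The 15 leave out Cry2, Bhlhe40 and Rorc and hold the called genes that prompted the test. Of the 18 genes on the list, 6 were called. Harvest times are not given, so libraries collected at different times of day and a genotype effect cannot be told apart for these genes. An effect of genotype on healing stays open for the other genes, in a comparison where leaving out 1 library gave 10 to 426 calls. The calls became 426, 10 and 34 without KO 4 weeks replicates 1, 2 and 3. On the second principal component replicates 2 and 3 (-74.7 and -109.9) stood apart from KO 4 weeks replicate 1 (45.5). The WT 4 weeks libraries were at 80.1, -17 and 56.3. What parts the KO libraries was not tested, and the 220 calls cannot be told apart from it.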

How the results depend on the processing

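The fits without KO uninjured replicates 1 and 2 together, the endothelium covariate and the averaged genotype effect were chosen after the data were seen. DESeq2 size factors in edgeR and an absolute log2 fold change of at least 1 kept all 11 counts of called genes within 1.5 times. DESeq2's Wald test called 2841 genes for WT at 2 weeks against uninjured, 339 for WT 4 against 2 weeks, 3000 and 2350 for KO at 2 and 4 weeks against uninjured, 308 for KO 4 against 2 weeks, 342, 414 and 1022 for KO against WT in uninjured, 2-week and 4-week tendon, and 250 and 702 for the differences in response at 2 and 4 weeks. In the same order limma voom called 4571 for WT at 2 weeks, 5837 for WT at 4 weeks, 2321 for WT 4 against 2 weeks, 1029 and 748 for KO against uninjured, 2, 742 and 2384 for KO against WT, and 260 for the difference at 4 weeks. With only the groups compared in the fit the counts were 2754 and 3828 for WT, 168 for WT 4 against 2 weeks, 256 and 103 for KO, 0 for KO 4 against 2 weeks, 0 for KO against WT uninjured, 91 at 4 weeks, and 0 for both differences in response. Without the low-count filter they were 1 for KO 4 against 2 weeks, 42 and 8 for KO against WT in uninjured and 2-week tendon and 42 for the difference at 4 weeks. The skeletal muscle covariate gave 53 and 728 for WT, 0 and 1 for KO, 2 for KO against WT uninjured, and 0 and 4 for the differences. Without KO uninjured replicates 1 and 2 together the counts were 778 and 401 for KO, 12 for KO against WT uninjured and 10 for the difference at 2 weeks; the endothelium covariate gave 7 for KO against WT uninjured and 86 at 4 weeks, and summing same-numbered uninjured libraries gave 2 for the difference at 2 weeks. Where a count here is 0, the edgeR fit of all libraries had 4666 genes at an unadjusted p under 0.05 for KO at 2 weeks, 2057 for KO 4 against 2 weeks, 1658 for KO against WT uninjured, and 1833 and 2449 for the differences. Leaving out 1 library gave 838 to 1469 for WT at 2 weeks, 1268 to 1902 for WT at 4 weeks, 0 to 4 for WT 4 against 2 weeks, 926 to 1640 and 540 to 1108 for KO against uninjured, 0 to 13 for KO 4 against 2 weeks, 3 to 134, 0 to 46 and 10 to 426 for KO against WT, and 0 to 30 and 0 to 119 for the differences. The 142 list calls became 0 with an estimated correlation and 43 with fry. The 7 calls near Serpine1 at 4 weeks became 4 with a window of 5 Mb and 12 with 20 Mb, and the correlations between genotypes became 0.736 and 0.75 for genes of at least 10 CPM. Fewer libraries or fewer genes are part of how some of these settings are built. Fits of only the groups compared take the spread from those groups alone. The sum of the tested skeletal muscle genes on the TMM scale did not overlap between uninjured and injured libraries. Fits with the list's sum as covariate therefore cannot part injury from that sum. For the rest the cause was not tested.

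Of the 335 values of named genes, 331 kept their direction and their side of the threshold with DESeq2 size factors, 245 with limma voom, 316 without a filter and 103 with the muscle covariate; 81 lost their call with limma voom and 219 with the muscle covariate. Some of the 335 had no adjusted p in the next 2 settings. Of those that had one, 293 were kept, 20 gained a call and 1 lost it with the DESeq2 Wald test, and 205 were kept, 5 gained a call and 109 lost it with only the groups compared. Of the values with 1 library left out, 1557 were kept, 590 lost their call, 12 gained one and 1 reversed. Summing same-numbered uninjured libraries, in the contrasts that use them, kept 258 values, while 34 lost their call and 2 gained one. With the skeletal muscle covariate these log2 fold changes reversed: for KO at 2 weeks Krt14 to 18.41, Ly6d to 7.27, Tuba8 to 8.05, Grhl1 to 7.51, Rab25 to 11.86, Tcirg1 to -0.038, Sfn to 2.54 and Ier2 to 0.13, and for KO at 4 weeks Lor to 2.51, Tuba8 to 3.84, Slurp2 to 1.57, Grhl1 to 3.53 and Aloxe3 to 7.05. On the TMM scale the sum of the tested list members did not overlap between uninjured (137 to 248 CPM) and injured libraries (347 to 826 CPM). The covariate was the log2 of the whole list's sum before TMM. A fit with this covariate therefore cannot part injury from the muscle sum, and neither these reversals nor the lost calls show an effect of muscle content. Krt10 in KO at 2 weeks ran from -8.65 to 0.12 when 1 library was left out, the latter without KO uninjured replicate 2. Without KO uninjured replicates 1 and 2 together Krt10 at 2 weeks read 0.032, and at 4 weeks Lgals7 read 0.53, Alas2 1.53, Hba-a1 1.71 and Hba-a2 2.22. No paired analysis was possible because replicate numbers were given in accession order and pair nothing, and no label pairs libraries across groups. The title number 3 recurs in both uninjured groups, on tendons of mice of different genotypes. Alternative pseudocounts for normalized values were not run, since the file holds counts. At this depth 3 counts are 0.121 to 0.307 CPM, below which differences were not detectable.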

Other observations

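The gene lists were fixed before the data were examined, and no test reported in this part was chosen after the result was seen. Immediate early genes in WT had 5 of 24 down at 2 weeks, and 11 down and 1 up adjusted over the list alone (adjusted p = 0.00388, and adjusted p = 0.773 with an estimated correlation), and 6 down at 4 weeks, and 10 adjusted over the list alone (adjusted p = 0.00828, and adjusted p = 0.783 with an estimated correlation). Their sum was 8630, 4250 and 3360 CPM in WT uninjured replicates 1, 2 and 3, against 2220, 2760 and 1890 CPM at 2 weeks and 1440, 3070 and 2400 CPM at 4 weeks. Dusp1, a phosphatase that ends MAP kinase signals, read -2.46 ± 0.62 at 2 weeks and Klf2 -1.84 ± 0.40 at 4 weeks. Heat shock genes were called once, between uninjured KO and WT, with 2 of 15 up adjusted over the list alone (adjusted p = 0.0273, and adjusted p = 0.587 with an estimated correlation). Their sum was 2040, 2900 and 2370 CPM in KO uninjured replicates 1, 2 and 3 and 2060, 1990 and 2060 CPM in WT, highest in the library with 50200 CPM of keratinocyte genes. The chaperone genes Hspa1a and Hspa1b, near-identical copies, fell by 1.79 and 1.31 in WT at 2 weeks. The p53 targets and apoptosis list had 6 of 25 up in WT at 2 weeks, and 7 adjusted over the list alone (adjusted p = 0.00246, and adjusted p = 0.416 with an estimated correlation), with the caspases Casp3 at 1.80 ± 0.33 and Casp8 at 1.43 ± 0.21. Oxidative phosphorylation genes had 4 of 42 up in WT at 2 weeks, and 6 adjusted over the list alone (adjusted p = 0.00858, and adjusted p = 0.847 with an estimated correlation), and mitochondrially encoded transcripts had 2 of 10 down in WT at 4 weeks, and 3 adjusted over the list alone (adjusted p = 0.00679, and adjusted p = 0.782 with an estimated correlation). The unfolded protein response had 4 of 26 up in WT at 2 weeks both over all genes and adjusted over the list alone (adjusted p = 0.0497, and adjusted p = 0.82 with an estimated correlation), with the chaperone Calr at 0.60 ± 0.17. Glycolysis and hypoxia genes were called once, lower in KO than WT at 2 weeks with no member passing over all genes or adjusted over the list alone (median -0.41, adjusted p = 0.0367, and adjusted p = 0.836 with an estimated correlation). The growth factor Vegfa rose by 3.52 ± 0.69 in WT at 2 weeks and Ndrg1, a stress response gene, read -2.06 ± 0.29. The neutrophil list was called once, higher in uninjured KO with 2 of 5 up adjusted over the list alone (median 7.06, or 5.19 with groups at 0 set to 3 counts, adjusted p = 0.000214, and adjusted p = 0.192 with an estimated correlation). Its sum was 174, 98.3 and 8.33 CPM in KO uninjured replicates 1, 2 and 3 and 5.72, 5.53 and 31.1 CPM in WT.

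Several lists of signals and of muscle did not pass in any contrast. Wnt signalling had 8 of 41 genes up and 4 down in WT at 4 weeks, and 10 and 4 adjusted over the list alone (adjusted p = 0.545; lowest over the contrasts 0.205), with Wisp1, a matricellular Wnt target, at 4.44 ± 0.45 and Frzb at -6.20 ± 1.05. Growth factors and receptors had 11 of 38 up and 8 down in WT at 4 weeks, and 12 and 10 adjusted over the list alone (lowest adjusted p over the contrasts 0.321), with Ngf, nerve growth factor, at 3.53 ± 0.50 and Bmp4 at -3.14 ± 0.40. Skeletal muscle genes had 1 of 19 up (Tpm1, 1.49 ± 0.30) and 1 down (Atp2a1, the calcium pump of muscle, -3.58 ± 1.10) in WT at 4 weeks, with the same counts adjusted over the list alone (lowest adjusted p over the contrasts 0.103). Muscle regeneration genes had 1 of 5 up in WT at 4 weeks, and 3 adjusted over the list alone (lowest adjusted p over the contrasts 0.059), with Myl4, an embryonic myosin light chain, at 1.49 ± 0.36. Osteoblast markers passed between KO and WT at 4 weeks with a median of 1.91 (adjusted p = 0.0285, and adjusted p = 0.439 with an estimated correlation), with none of 15 passing over all genes or adjusted over the list alone. Their sum went the other way, at 10400, 3900 and 3790 CPM in KO 4 weeks replicates 1, 2 and 3 and 11800, 9860 and 9360 CPM in WT. Runx2, the master regulator of bone formation, rose by 2.33 ± 0.41 in WT at 2 weeks. Pericyte and smooth muscle markers had a median of 4.00 between KO and WT at 2 weeks, with none of 13 passing over all genes or adjusted over the list alone (adjusted p = 0.000533, and adjusted p = 0.667 with an estimated correlation). Their sum was 585, 897 and 2780 CPM in KO 2 weeks replicates 1, 2 and 3 and 581, 458 and 549 CPM in WT, so KO replicate 1 was close to WT. Fatty acid oxidation was called once, in the difference in response at 4 weeks, with 1 of 22 up adjusted over the list alone; Eci1, an enzyme of the pathway, read -1.30 ± 0.18 in WT at 4 weeks.

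In a principal component analysis the first 3 components held 24.9%, 15.7% and 12.5% of the variance. The first parted uninjured libraries (77.8 to 127.6) from injured ones (-67 to -26.2), and KO uninjured replicate 2 stood apart on the third at -168.1. The second set KO 2 weeks replicates 2 and 3 (-70.3 and -93.4) and KO 4 weeks replicates 2 and 3 (-74.7 and -109.9) apart from all other libraries (-34.4 to 80.1). Replicate 1 of both KO groups (30.2 and 45.5) lay within the range of the injured WT libraries (-17 to 80.1). Mast cell genes summed to 1.59, 95.4 and 144 CPM in KO 2 weeks replicates 1, 2 and 3 and 0.714, 88.5 and 71.8 CPM in KO 4 weeks replicates 1, 2 and 3. Collagens summed to 108000, 56000 and 58100 CPM in KO 4 weeks replicates 1, 2 and 3, against 93400 to 104000 CPM in WT. In KO 2 weeks replicates 1, 2 and 3 they summed to 61300, 62300 and 52800 CPM. Every one of these was below the WT 2-week sums of 87000, 82000 and 76500 CPM. The cause was not tested. In simulated data with known changes, 14%, 66%, 80% and 92% of the genes changed 2-fold, 4-fold, 8-fold and 16-fold were recovered between KO and WT at 4 weeks, with 8 false calls. For the difference in the 4-week response 8%, 48%, 62% and 86% were recovered, with 3 false calls. The simulated genes were drawn independently, with equal means in all groups apart from the changes in KO 4 weeks. Changes were put only into genes averaging at least 1 CPM, and a further set shifted 2-fold was left out of the false calls. The real libraries differ in composition within groups, so these shares need not hold for them.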
